A study of Mus musculus with 6 samples.

How the data were processed

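RNA from macrophages sorted from the spleen of C57BL/6 mice was sequenced in 6 libraries, 1 for each of 3 subsets (Ly6ChiF480lo, Ly6CloF480lo and Ly6CloF480hi) in normal mice (day 0) and in mice with T-ALL (day 15 after transplantation of 1000000 GFP-positive leukemia cells without irradiation), per the labels. RNA was extracted with a QIAGEN RNeasy kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The deposited values are FPKM, for which reads were aligned with Bowtie2 version 2.2.5 and quantified with RSEM, per the submitters' processing notes. The genome build, the annotation and the RSEM version are not given in the sources used here. The files list Entrez gene identifiers and FPKM to 2 decimals, and the lowest listed value is 0.01. A gene missing from a file was taken as 0. Of 16058 identifiers 16017 (99.7%) were given a symbol from a RefSeq table of the GRCm38.p6 assembly, used for names only, and 41 were kept without one.

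FPKM sums ranged from 494558 to 583298 per library, the 50 highest genes held 22.7% to 27.9% of each sum, and median-ratio factors lay between 0.910 and 1.08. Depth was recovered from the FPKM values themselves. Each value of a gene is a whole number of fragments divided by transcript length and depth, so the spacing of low values in 355 to 393 genes with one annotated transcript length per library gives the depth. The estimates were 7410000, 7870000 and 7600000 fragments for normal Ly6ChiF480lo, Ly6CloF480lo and Ly6CloF480hi, and 6640000, 8440000 and 8700000 for T-ALL in the same order. Tested on simulated libraries, the estimate was at most 0.251% off. Annotated length is longer than effective length, so the true depth is somewhat higher. Lengths and GC content came from GENCODE M21 transcripts.

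Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 and statmod 1.5.0 (jsonlite 2.0.0 to read the labels). Depth and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes with at least 1 FPKM in at least 2 of the 6 libraries were tested (11616). A linear model with subset and state was fitted to all 6 libraries with a trended and robust prior, which leaves 2 residual degrees of freedom (median total 6.23). The state term gave T-ALL against normal, with subset as a block, and contrasts of the subset terms gave the 3 comparisons between subsets, with state as a block. Tests were two-sided, p was adjusted by the method of Benjamini and Hochberg over the tested genes, and an adjusted p under 0.05 passed. Each SE is that of the moderated fit. An unpaired exact test of 3 against 3 libraries could not have gone below p = 0.1. Within a subset there is 1 library per state, so no test was made. The log2 ratio was computed there, and 2-fold differences were counted among genes of at least 5 FPKM in 1 of the 2 libraries. The state changes of the subsets were compared by correlation over genes and by the overlap of 2-fold genes beside the product of the list sizes over the number of genes.

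Gene lists, 26 of pathways and 14 of cell types, were written from general knowledge before the data were examined, as were the design, the tests, the other settings to be tried and the rule for naming genes. Of their 622 symbols 605 were found and 571 tested, and 39 of 40 lists had at least 3 tested genes. Lists were tested with limma camera at a preset correlation between genes of 0.01, with adjustment over the 39 lists. Camera with an estimated correlation and fry, a rotation test of the same package, were run beside it. The form with an estimated correlation refers each list to the 2 residual degrees of freedom of the fit, which raises its p. Within subsets the median log2 of a list was ranked among 10000 random lists of the same size matched on deciles of mean expression. For each list the members were also adjusted over the list alone.

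Genes named in the text were chosen by rule. In every comparison these were Ly6c1, Ly6c2, Adgre1, Irf7, Ptprc, Cd68, Csf1r and Itgam. For each tested comparison they were the 10 highest and 10 lowest log2 changes among genes that passed, kept one direction in every pair and had at least 10 FPKM in 1 library. Within a subset they were the 10 highest and 10 lowest of genes with at least 10 FPKM in 1 of the 2 libraries. For lists they were up to 4 members with the largest absolute change and at least 5 FPKM in 1 library. Immunoglobulin and T cell receptor segments and genes known only by an identifier were skipped. A gene that this rule picks is not reported here.

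A branch for count files was not used because the files hold FPKM. The alternatives tried were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-ratio rescaling, quantile normalization, limma without trend and robust prior, a 2-fold threshold, no block, a fit on the 4 libraries of 2 subsets, and each library left out in turn. The fit was tested on simulated data with 200 of 11616 genes changed (20 runs). It recovered 99.4% of 2-fold and 100% of 4-fold changes between states, and 95.0% to 95.6% and 100% between subsets. There were 0 wrong signs, and 3.96% to 5.04% of calls were false. The simulated noise was independent between genes, its spread was set by expression level, and a change was equal in all pairs. Real genes vary more freely, so a gene that did not pass may still have changed 2-fold. Both forms of camera found a changed list of 20 independent genes in 20 of 20 runs and called an unchanged one in at most 1. These rates need not hold for correlated lists (0.978 for ribosomal genes). The raw reads and transcript isoforms were not analysed here.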

Results

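Splenic macrophages of 3 sorted subsets, Ly6ChiF480lo, Ly6CloF480lo and Ly6CloF480hi, were profiled once in normal mice and once in mice at day 15 after transplantation of T-ALL cells, which gave 6 libraries. The libraries listed 14225 to 14628 genes each, and 12987 genes were listed in all 6. The most abundant transcript was Cd74, the class II invariant chain, in the 3 normal libraries (15521, 20333 and 11137 FPKM in the order of subsets above) and in T-ALL Ly6CloF480lo (10657 FPKM). In T-ALL Ly6ChiF480lo it was S100a8, a calcium-binding protein of neutrophils and monocytes (21584 FPKM). In T-ALL Ly6CloF480hi it was the globin Hba-a1 (18610 FPKM). The depth recovered from the spacing of the FPKM values lay between 6640000 and 8700000 fragments per library. At that depth a gene of 10 FPKM with a 2 kb transcript carries a counting error of 7.58% to 8.67%, and a gene of 1 FPKM one of 24.0% to 27.4%. The labels do not say whether the 3 subsets of a state were sorted from separate mice, so each p-value measures only the spread between these sorted fractions.

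The sort markers followed the gates. Ly6c2, which encodes the monocyte antigen used for sorting, stood at 482 and 1405 FPKM in normal and T-ALL Ly6ChiF480lo, at 19.9 and 21.4 FPKM in Ly6CloF480lo, and at 11.8 and 19.8 FPKM in Ly6CloF480hi. Ly6c1, its close paralog, was low throughout (4.85 and 8.58 FPKM in Ly6ChiF480lo, at most 1.04 FPKM elsewhere), and the 2 genes share sequence. Adgre1, which encodes the second sort antigen, stood at 529 and 234 FPKM in normal and T-ALL Ly6CloF480hi against 86.6 and 47.3 FPKM in Ly6ChiF480lo and 86.7 and 74.7 FPKM in Ly6CloF480lo. Subset carried 60.7% of the variance of the 11616 tested genes, state 28.6% and the remainder 10.7%. The first principal component (42.7% of the variance) placed Ly6ChiF480lo at -35.5 and -53.0 and Ly6CloF480hi at 55.7 and 33.6 for normal and T-ALL. The second (30.2%) had the 3 normal libraries between 9.42 and 37.3 and the 3 T-ALL libraries between -39.1 and -7.25. The closest libraries of different state were normal and T-ALL Ly6CloF480lo (Pearson r = 0.957), and the furthest were normal Ly6CloF480hi and T-ALL Ly6ChiF480lo (r = 0.845).

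**Figure D1:**
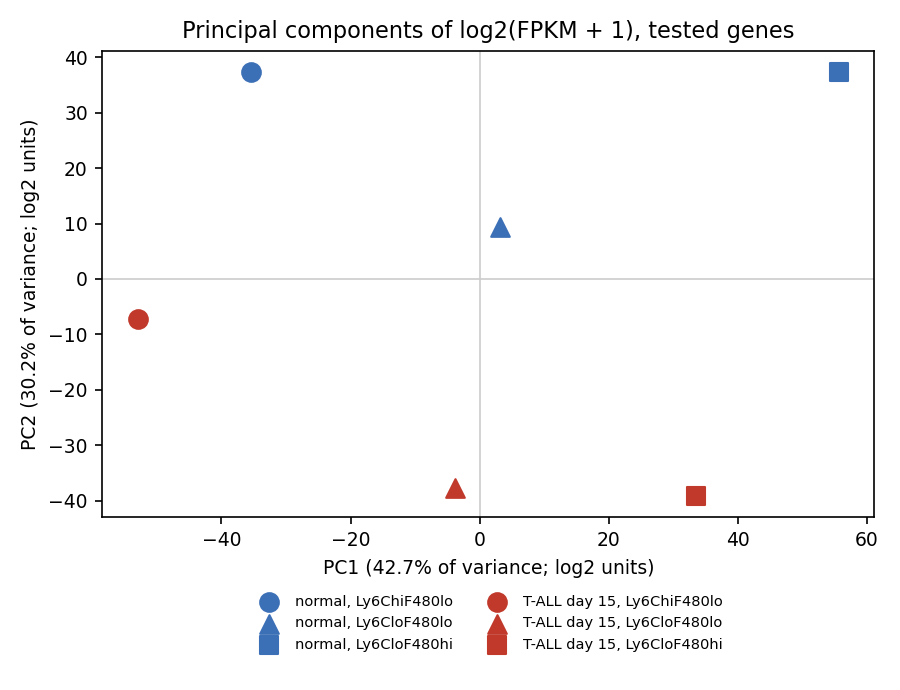
Scores of the 6 libraries on the first (42.7%) and second (30.2%) principal components of log2(FPKM + 1), with state shown by color and subset by symbol.

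In T-ALL against normal over the 3 subsets, 24 of 25 cell cycle and 7 of 10 myeloid progenitor genes rose and 9 of 20 immediate early and 16 of 24 red pulp macrophage genes fell (adjusted p = 0.581 with an estimated correlation for each of these lists). Mpo, the myeloperoxidase of granulocyte precursors, went from 101, 11.96 and 5.22 FPKM to 745, 149 and 32.6 FPKM (log2 2.95, SE 0.22, adjusted p = 0.00832, 3 libraries per state). Ctsg, a protease of the same granules, rose alongside it (19.95, 3.20 and 2.12 to 211, 49.5 and 13.1 FPKM; log2 3.03, SE 0.28). Atf3, a transcription factor induced by stress, fell from 84.2, 194 and 118 FPKM to 13.2, 20.3 and 25.1 FPKM (log2 -2.66, SE 0.21, adjusted p = 0.00832). Trf, which encodes the iron carrier transferrin, fell from 192, 119 and 1633 FPKM to 53.4, 38.2 and 387 FPKM (log2 -1.84, SE 0.17). In all, 1410 of 11616 genes passed, 952 higher and 458 lower, and 621 of them changed at least 2-fold (493 higher and 128 lower). The median change of all genes was -0.03, and 6723 genes (57.9%) kept one direction in all 3 subsets, against 25% for independent signs.

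Among the genes with the largest rise was Asns, the asparagine synthetase, at 8.29, 3.25 and 4.53 FPKM in normal and 31.8, 45.8 and 70.0 FPKM in T-ALL (log2 2.99, SE 0.36, adjusted p = 0.0116). The histone gene H2ac11, a member of a multigene family to which reads are hard to assign, was not listed in the 3 normal libraries, where it was taken as 0, and stood at 4.05, 15.8 and 17.7 FPKM in T-ALL (adjusted p = 0.00925). Red cell genes made up much of the rest: Aqp1, a water channel (2.73, SE 0.51), Rhd, a blood group antigen (2.73, SE 0.46), Hemgn (2.72, SE 0.59), Slc4a1, the band 3 anion exchanger (2.71, SE 0.58), and Car1, a carbonic anhydrase (2.68, SE 0.37), with adjusted p of 0.0285, 0.0240, 0.0399, 0.0391 and 0.0158. Prss34, a mast cell and basophil protease, rose from 3.72, 14.7 and 4.84 FPKM to 10.0, 163 and 63.7 FPKM (log2 2.70, SE 0.44, adjusted p = 0.0225). At the other end, Hspa1a, an inducible heat shock protein, fell from 196, 53.4 and 56.5 FPKM to 15.6, 19.9 and 9.43 FPKM (log2 -2.47, SE 0.39, adjusted p = 0.0207). Cd209a, a lectin of dendritic cells, fell from 217, 96.5 and 31.7 FPKM to 21.9, 24.5 and 9.54 FPKM (log2 -2.27, SE 0.31, adjusted p = 0.0138). Abca9 (-1.94, SE 0.28), the kinase gene Plk2 (-1.78, SE 0.16), Fcna (-1.67, SE 0.16), Tmem37 (-1.65, SE 0.27), the receptor kinase gene Axl (-1.65, SE 0.14) and the prostacyclin synthase gene Ptgis (-1.64, SE 0.34) also fell.

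The 8 genes named whatever their change did not pass between states. Irf7, the interferon regulatory factor, stood at 156, 79.5 and 151 FPKM in normal and 90.6, 67.9 and 91.2 FPKM in T-ALL (log2 -0.57, adjusted p = 0.0709). Ly6c2 had a log2 of 0.78 (adjusted p = 0.0998) and Ly6c1 of 0.18 (0.634), while the integrin gene Itgam had -0.16 (0.562). Adgre1 (-0.75, adjusted p = 0.0662), the pan-leukocyte gene Ptprc (-0.67, 0.0598), the lysosomal gene Cd68 (-0.82, 0.0556) and the growth factor receptor gene Csf1r (-0.72, 0.174) had lower values in T-ALL. Over 17 alternatives the adjusted p ran from 0.0363 to 0.695 for Adgre1, from 0.0267 to 0.381 for Cd68, from 0.0214 to 0.634 for Csf1r, from 0.0490 to 0.864 for Ly6c2, from 0.0494 to 0.374 for Irf7 and from 0.0438 to 0.213 for Ptprc. Adgre1, Cd68 and Csf1r passed, with log2 of -1.02, -1.06 and -1.19, when the normal Ly6CloF480lo library was left out (adjusted p = 0.0390, 0.0289 and 0.0226) or the T-ALL one of that subset (0.0363, 0.0267 and 0.0214). Ly6c2 passed without the T-ALL Ly6CloF480lo library (log2 1.12, adjusted p = 0.0490), and Irf7, Ptprc and Cd68 after quantile normalization (0.0494, 0.0438 and 0.0435).

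Leaving out single libraries changed how many genes passed in T-ALL against normal over the 3 subsets. Without normal Ly6CloF480hi 283 genes passed and without T-ALL Ly6CloF480hi 318, against 893 and 886 without normal Ly6ChiF480lo or Ly6CloF480lo, and 913 and 923 without T-ALL Ly6ChiF480lo or Ly6CloF480lo. With subset as a block, the library left alone in its subset adds nothing to the state change, so leaving out either library of a pair gave the same log2. The red cell genes Aqp1, Rhd, Hemgn and Slc4a1 kept a large change but not their calls. Without either Ly6CloF480lo library their log2 was 2.503, 2.47, 2.31 and 2.35 (adjusted p = 0.162, 0.139, 0.205 and 0.203 without normal, 0.159, 0.138, 0.205 and 0.201 without T-ALL). Without either Ly6CloF480hi library it was 2.14, 2.23, 2.14 and 2.11 (0.155, 0.144, 0.213 and 0.207 without normal, 0.0854, 0.0777, 0.135 and 0.129 without T-ALL). Prss34 had 2.35 without normal (adjusted p = 0.129) or T-ALL Ly6CloF480lo (0.127) and 2.31 without normal (0.148) or T-ALL Ly6CloF480hi (0.0785), and did not pass. Ptgis had -1.56 without normal (adjusted p = 0.113) or T-ALL Ly6CloF480lo (0.115) and -1.23 without normal (0.126) or T-ALL Ly6CloF480hi (0.115). Asns and Car1 had 2.75 and 2.57 and were lost without normal (adjusted p = 0.0711 and 0.0998) or T-ALL Ly6CloF480lo (0.0609 and 0.0977), and 2.64 and 2.21 without normal Ly6CloF480hi (0.0804 and 0.0628). Hspa1a and Abca9 had -2.47 and -1.76 and were lost without normal (0.138 and 0.0810) or T-ALL Ly6CloF480hi (0.0707 and 0.0645), and H2ac11 was lost without normal Ly6CloF480hi (0.0514). Over all 17 alternatives the highest adjusted p was 0.343 for Aqp1, 0.346 for Rhd, 0.316 for Hemgn, 0.375 for Slc4a1 and 0.251 for Prss34. It was 0.575 for Ptgis, 0.0804 for Asns, 0.3997 for Car1, 0.138 for Hspa1a, 0.119 for Abca9 and 0.0514 for H2ac11. The lowest lay between 0.00396 and 0.0116. Without the subset block Mpo, Ctsg, Trf, Fcna, Axl, Cd209a and Tmem37 did not pass either (adjusted p = 0.340, 0.250, 0.482, 0.638, 0.631, 0.194 and 0.471), nor did Tmem37 without a filter on low values (0.0590).

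Cell cycle genes rose almost without exception. Of 25 tested members 24 rose, 0 fell and 1 (Tyms) did not pass, and the counts were the same when p was adjusted over the list alone (median log2 1.87, camera adjusted p = 2.0e-19, adjusted p = 0.581 with an estimated correlation). Ccnb1, a mitotic cyclin, went from 9.61, 9.45 and 7.97 FPKM to 53.2, 53.8 and 75.3 FPKM (log2 2.61, SE 0.18). Rrm2, a subunit of ribonucleotide reductase, Birc5, which encodes survivin, and Ccna2, a cyclin of S and G2 phase, rose by log2 2.495, 2.49 and 2.45 (SE 0.20, 0.21 and 0.24; each with an adjusted p = 0.00832). Mki67, the proliferation marker, rose by 1.87. The myeloid progenitor list (medians 2.46, 2.45 and 1.36 in Ly6ChiF480lo, Ly6CloF480lo and Ly6CloF480hi) and the plasma cell list (1.20, 0.76 and 2.10) moved with the cell cycle list in all 3 subsets. The megakaryocyte and platelet list did so with smaller values (0.37, 0.91 and 0.98). The erythroid list moved with it mainly in the Ly6Clo subsets: its median change was 0.29 in Ly6ChiF480lo, 2.87 in Ly6CloF480lo and 3.02 in Ly6CloF480hi, against 1.84, 1.57 and 2.29 for the cell cycle list. The T cell list moved the other way in Ly6ChiF480lo and Ly6CloF480lo (medians -0.59 and -0.32) and with it in Ly6CloF480hi (0.88).

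Some markers of blood cell precursors and secretory cells also rose. Of 16 erythroid genes 6 rose, 0 fell and 10 did not pass (15 rose and 0 fell over the list alone, median log2 2.11, camera adjusted p = 6.6e-07, adjusted p = 0.581 with an estimated correlation), led by Slc4a1 and Car1, by Klf1, the erythroid transcription factor (2.59, SE 0.49, adjusted p = 0.0306), and by Car2 (14.0, 38.0 and 66.0 to 22.2, 389 and 800.4 FPKM; 2.51, SE 0.56, adjusted p = 0.0430). Of 10 myeloid progenitor genes 7 rose, 0 fell and 3 did not pass (8 and 0 over the list alone, median 2.07, camera adjusted p = 6.5e-06, adjusted p = 0.581 with an estimated correlation), with Ctsg, Mpo, the serine protease gene Prtn3 (2.54, SE 0.22, adjusted p = 0.00832) and Ms4a3 (2.43, SE 0.30, adjusted p = 0.0113) at the front. Of 7 plasma cell genes 5 rose, 0 fell and 2 did not pass (5 and 0 over the list alone). Its median change was 1.46 (camera adjusted p = 4.6e-04, adjusted p = 0.581 with an estimated correlation). Jchain, the joining chain of polymeric antibodies, rose from 4617, 376 and 187 FPKM to 10138, 941 and 876 FPKM (log2 1.56, SE 0.28, adjusted p = 0.0248). Mzb1 (1.90, SE 0.26), Derl3 (1.84, SE 0.16) and Sdc1 (1.46, SE 0.26) rose with it. Of 8 megakaryocyte and platelet genes 2 rose, Pf4 (1.52, SE 0.36, adjusted p = 0.0471) and Itgb3 (1.00, SE 0.15, adjusted p = 0.0185), 0 fell and 6 did not pass (7 and 0 over the list alone). The list had a median of 0.77 (camera adjusted p = 7.2e-04, adjusted p = 0.581 with an estimated correlation).

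Ribosomal and respiratory chain genes had higher values in T-ALL, though few of them passed singly. The ribosomal medians were 1.01 and 1.27 in Ly6ChiF480lo and Ly6CloF480hi but 0.23 in Ly6CloF480lo (percentile 83.9 of random lists, 0 of 34 genes at 2-fold). Rps2 rose from 441, 1105 and 525 FPKM to 1149, 1633 and 1623 FPKM (log2 1.19, SE 0.27, adjusted p = 0.0417). Of 34 ribosomal protein genes only Rps2 and Rpl5 rose, 0 fell and 32 did not pass, while 31 rose and 0 fell over the list alone (median 0.85, camera adjusted p = 1.7e-10, adjusted p = 0.581 with an estimated correlation). Of 24 oxidative phosphorylation genes 7 rose, 0 fell and 17 did not pass (22 and 0 over the list alone). Its median change was 0.57 (camera adjusted p = 1.2e-08, adjusted p = 0.581 with an estimated correlation). Cox7a2 (0.89, SE 0.15, adjusted p = 0.0239), Atp5b (0.86, 0.0409), Cox5b (0.74, 0.0472) and Cyc1 (0.74, 0.0368), subunits of complexes III to V, were among them. Of 17 glycolysis and hypoxia genes 4 rose, 0 fell and 13 did not pass, and the list was not called (4 and 1 over the list alone). The list had a median of 0.18 (camera adjusted p = 0.228, adjusted p = 0.581 with an estimated correlation). The 4 were Gapdh (1.03, SE 0.21), Pgk1 (0.86), Ldha (0.82) and Pgam1 (0.59). Of 16 endoplasmic reticulum and heat stress genes 4 rose, 1 fell and 11 did not pass (8 and 2 over the list alone). Its median change was 0.64 (camera adjusted p = 0.0273, adjusted p = 0.581 with an estimated correlation). The chaperone gene Hsp90b1 (1.18, SE 0.23, adjusted p = 0.0295) and the disulfide isomerase gene Pdia4 (1.13, SE 0.23, adjusted p = 0.0329) rose and Hspa1a fell. This list was not called after quantile normalization or without normal Ly6ChiF480lo or T-ALL Ly6ChiF480lo, while the ribosomal, respiratory chain and cell cycle lists kept their calls after quantile normalization.

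Red pulp macrophage genes had lower values in T-ALL, with list medians of -0.80 in Ly6ChiF480lo, -0.91 in Ly6CloF480lo and -1.19 in Ly6CloF480hi, where they are most abundant. Slc40a1, the iron exporter ferroportin, went from 61.6, 65.7 and 1597 FPKM to 28.4, 23.4 and 396 FPKM (log2 -1.52, SE 0.20, adjusted p = 0.0138). Vcam1, an adhesion molecule of these cells, went from 60.7, 80.4 and 2046 FPKM to 25.6, 24.9 and 701 FPKM (log2 -1.47, SE 0.16, adjusted p = 0.00925). Of 24 red pulp and iron genes 0 rose, 16 fell and 8 did not pass (1 and 17 over the list alone). The list had a median of -1.02 (camera adjusted p = 2.7e-09, adjusted p = 0.581 with an estimated correlation). The largest falls were in Trf, Fcna (60.5, 88.7 and 1509.8 to 20.1, 22.1 and 526 FPKM), Axl (30.2, 20.96 and 557 to 9.94, 6.15 and 158 FPKM) and Slc40a1. Hmox1, the heme oxygenase, fell by 1.31 and Spic, the transcription factor of red pulp macrophages, by 0.82. Of 15 general macrophage genes 0 rose, 4 fell and 11 did not pass (0 and 6 over the list alone, median -0.64, camera adjusted p = 2.8e-04, adjusted p = 0.581 with an estimated correlation), among them the receptor kinase gene Mertk (-1.17, SE 0.18, adjusted p = 0.0168) and the Fc receptor gene Fcgr1 (-1.10, SE 0.25, adjusted p = 0.0410). In Ly6CloF480hi the erythroid list had a median change of 3.02 beside that of the red pulp list (-1.19). The plasma cell (2.10), myeloid progenitor (1.36), megakaryocyte and platelet (0.98) and T cell lists (0.88) were also higher there, and the B cell list was at 0.07.

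Phagocytosis, complement and lipid handling genes followed in part. Of 25 phagocytosis and lysosome genes 1 rose, 7 fell and 17 did not pass (1 and 10 over the list alone, median -0.46, camera adjusted p = 5.8e-05, adjusted p = 0.581 with an estimated correlation), with Fcgr4, another Fc receptor gene, as the 1 that rose (1.30, SE 0.30, adjusted p = 0.0430). Of 12 complement genes 2 rose, 4 fell and 6 did not pass, and the list was not called (2 and 5 over the list alone). Its median change was -0.53 (camera adjusted p = 0.238, adjusted p = 0.581 with an estimated correlation). The 4 that fell were C1qa (-1.15, SE 0.20), C1qc (-1.04), C1qb (-0.996) and Cfp (-0.95). Apoe, a lipid carrier, fell from 2183, 1003 and 4198 FPKM to 404, 475 and 1647 FPKM (log2 -1.62, SE 0.31, adjusted p = 0.0291), and the exporter gene Abca1 fell by 0.86. They were the only 2 of 11 cholesterol efflux genes that passed (0 rose and 9 did not pass, 0 and 2 over the list alone). The list had a median of -0.35 (camera adjusted p = 0.115, adjusted p = 0.691 with an estimated correlation). Of 14 cholesterol synthesis genes 0 passed, by either adjustment (median -0.20, camera adjusted p = 0.329, adjusted p = 0.817 with an estimated correlation). Without normal or T-ALL Ly6CloF480lo the cholesterol efflux list was called lower.

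Immediate early genes were lower in T-ALL in each subset (list medians -0.58, -0.95 and -1.33). Dusp1, a phosphatase that acts on MAP kinases, fell from 369, 348 and 419.9 FPKM to 136, 126 and 124 FPKM (log2 -1.55, SE 0.17, adjusted p = 0.00898). Zfp36, which promotes decay of cytokine transcripts, fell by 1.39 (SE 0.21, adjusted p = 0.0168) and Junb, an AP-1 subunit, by 1.34. Egr1 had a log2 of -1.45 and did not pass (adjusted p = 0.0705). Of 20 immediate early genes 0 rose, 9 fell and 11 did not pass (0 and 16 over the list alone, median -1.03, camera adjusted p = 4.4e-08, adjusted p = 0.581 with an estimated correlation), with Atf3 the lowest. Of 24 pattern recognition genes 0 rose, 3 fell and 21 did not pass (0 and 7 over the list alone, median -0.43, camera adjusted p = 4.2e-04, adjusted p = 0.581 with an estimated correlation), including the inflammasome sensor gene Nlrp3 (-1.37, SE 0.17, adjusted p = 0.0108) and Irak2 (-0.76, adjusted p = 0.0312). Of 14 NF-kB genes 0 rose, 3 fell and 11 did not pass (0 and 6 over the list alone, median -0.38, camera adjusted p = 0.00815, adjusted p = 0.581 with an estimated correlation): Rel (-1.02, SE 0.16), Icam1 (-0.67) and Tnfaip3 (-0.63). Of 18 JNK and p38 genes only Mapk14 fell (-0.64, SE 0.14, adjusted p = 0.0396), 0 rose and 17 did not pass (0 and 0 over the list alone). Its median change was -0.12 (camera adjusted p = 0.253, adjusted p = 0.581 with an estimated correlation).

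Some antigen presentation and dendritic cell genes fell, 5 of 14 in each list (adjusted p = 0.581 with an estimated correlation for each). H2-DMb1, which loads class II molecules, fell by 0.92 (SE 0.20, adjusted p = 0.0397), and Ciita, the class II transactivator, went from 70.5, 160.2 and 73.6 FPKM to 25.3, 84.5 and 56.9 FPKM (log2 -0.91, SE 0.22, adjusted p = 0.0482). H2-Ab1, a class II chain, stood at 3635, 5909 and 2906 FPKM in normal and 1448, 3121 and 2021 FPKM in T-ALL and did not pass (log2 -0.92, adjusted p = 0.0693). Of 14 class II presentation genes 0 rose, 5 fell and 9 did not pass (0 and 13 over the list alone). The list had a median of -0.81 (camera adjusted p = 1.9e-06, adjusted p = 0.581 with an estimated correlation). Cd80 (-1.18, SE 0.17, adjusted p = 0.0158) and Cd86 (-0.90, SE 0.18, adjusted p = 0.0306), the costimulatory ligands, were among the 5. Of 14 conventional dendritic cell genes 0 rose, 5 fell and 9 did not pass (0 and 10 over the list alone, median -0.71, camera adjusted p = 3.4e-05, adjusted p = 0.581 with an estimated correlation), with Cd209a, the cytokine receptor gene Flt3 (-1.08, SE 0.20, adjusted p = 0.0273) and Clec9a (-1.07, SE 0.19, adjusted p = 0.0234) at the front. The class II list had medians of -1.03, -0.88 and -0.42 in Ly6ChiF480lo, Ly6CloF480lo and Ly6CloF480hi, and the B cell list was lower with it in the first 2 (-0.51, -0.54 and 0.07).

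Genes of interferon responses and of macrophage polarization were mixed. Isg20, an interferon-induced exonuclease, rose from 59.7, 30.9 and 20.3 FPKM to 189.5, 64.6 and 128 FPKM (log2 1.76, SE 0.29, adjusted p = 0.0214). Mx2 (-0.86, SE 0.21, adjusted p = 0.0475), Oas2 (-0.84, SE 0.14, adjusted p = 0.0223) and Ifit3 (-0.80, SE 0.19, adjusted p = 0.0448), antiviral effectors, fell. Of 30 type I interferon genes 2 rose, 4 fell and 24 did not pass, and the list was not called (3 and 7 over the list alone). Its median change was -0.28 (camera adjusted p = 0.0662, adjusted p = 0.581 with an estimated correlation). It was called lower after quantile normalization and without any of normal or T-ALL Ly6CloF480lo and normal or T-ALL Ly6CloF480hi. Of 19 interferon gamma genes Igtp rose (0.67, SE 0.14, adjusted p = 0.0344), Ciita fell and 17 did not pass (2 and 1 over the list alone, median 0.29, camera adjusted p = 0.114, adjusted p = 0.581 with an estimated correlation); the list was called higher without normal or T-ALL Ly6CloF480hi. Of 15 M1 genes 0 rose, 4 fell and 11 did not pass (2 and 4 over the list alone, median -0.16, camera adjusted p = 0.329, adjusted p = 0.581 with an estimated correlation), with the prostaglandin synthase gene Ptgs2 lowest (-1.50, SE 0.27, adjusted p = 0.0247) and Fpr2 at 1.32 (adjusted p = 0.0517). Of 21 M2 genes 1 rose, 5 fell and 15 did not pass (1 and 10 over the list alone). The list had a median of -0.49 (camera adjusted p = 0.00844, adjusted p = 0.581 with an estimated correlation). Mrc1, the mannose receptor (15.5, 13.1 and 307 to 7.54, 3.22 and 75.2 FPKM; log2 -1.57, SE 0.22), and Cd163, the hemoglobin scavenger receptor (-1.50, SE 0.22), fell, while Il10, an inhibitory cytokine, rose from 0.31, 1.68 and 1.53 FPKM to 7.58, 4.74 and 6.65 FPKM (1.80, SE 0.32, adjusted p = 0.0241).

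Lists for trafficking, growth factors and immune suppression were not called. Ccr2, the receptor for monocyte chemoattractants, fell by 1.26 (SE 0.29, adjusted p = 0.0421) and Cxcr3 rose by 1.37 (SE 0.23, adjusted p = 0.0228). Of 19 migration genes 1 rose, 3 fell and 15 did not pass (1 and 4 over the list alone, median -0.18, camera adjusted p = 0.0939, adjusted p = 0.581 with an estimated correlation); the list was called lower after quantile normalization and without normal or T-ALL Ly6CloF480hi. Of 12 chemokine genes 0 passed by either adjustment (median -0.35, camera adjusted p = 0.253, adjusted p = 0.581 with an estimated correlation). Of 16 growth and angiogenic factor genes 2 rose, 2 fell and 12 did not pass (2 and 3 over the list alone, median -0.40, camera adjusted p = 0.329, adjusted p = 0.614 with an estimated correlation), with the matrix protein gene Spp1 higher (1.51, SE 0.31, adjusted p = 0.0345) and the elastase gene Mmp12 (-1.36, SE 0.28, adjusted p = 0.0345) and the growth factor gene Igf1 (-1.09, SE 0.21, adjusted p = 0.0290) lower. Of 18 checkpoint and suppression genes 1 rose, 2 fell, Havcr2 (-0.91) and Sirpa (-0.70), and 15 did not pass (1 and 4 over the list alone, median -0.01 and mean 0.0006, camera lower, adjusted p = 0.614, adjusted p = 0.773 with an estimated correlation).

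Few markers of other blood cells passed over the 3 subsets. Cd4, a coreceptor also found on some dendritic cells, fell by 0.88 (SE 0.17, adjusted p = 0.0308) and was the only 1 of 18 T cell genes that passed (0 rose and 17 did not pass, 0 and 1 over the list alone, median -0.02 and mean 0.08, camera lower, adjusted p = 0.726, adjusted p = 0.988 with an estimated correlation). Of 6 Notch target genes Hes1 fell (-0.74, adjusted p = 0.0260), 0 rose and 5 did not pass (median -0.05, camera adjusted p = 0.973). Of 13 neutrophil genes 0 passed by either adjustment (median -0.22, mean -0.04 and camera higher, adjusted p = 0.9995). Of 15 classical monocyte genes 1 rose, Hp, which binds free hemoglobin (1.19, SE 0.17, adjusted p = 0.0155), 1 fell, Ccr2, and 13 did not pass (3 and 2 over the list alone, median -0.08, mean 0.02 and camera higher, adjusted p = 0.839). Of 17 patrolling monocyte genes 0 rose, 2 fell, Nr4a1 (-1.16, SE 0.17) and Klf2 (-0.88, SE 0.13), and 15 did not pass (0 and 2 over the list alone, median 0.12, mean 0.02, camera adjusted p = 0.871). Without normal or T-ALL Ly6CloF480hi the T cell list was called lower, and without normal or T-ALL Ly6ChiF480lo the neutrophil list was.

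**Figure D2:**
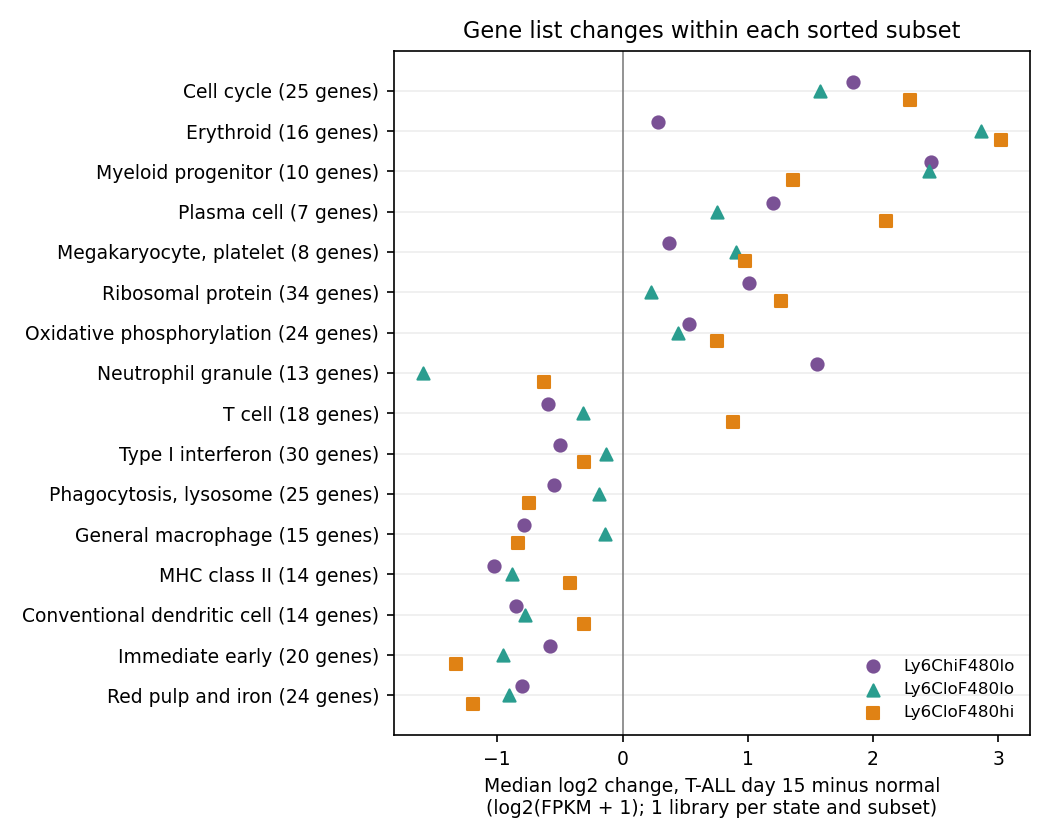
Median log2 change, T-ALL minus normal, of 16 gene lists in each subset (circles Ly6ChiF480lo, triangles Ly6CloF480lo, squares Ly6CloF480hi).

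Within Ly6ChiF480lo, granule genes were among those with the largest increases. Slpi, a protease inhibitor, went from 157 FPKM in normal to 3449 FPKM in T-ALL (log2 4.45, 1 library per state) and Retnlg, a resistin-like gene of neutrophils, from 28.2 to 234 FPKM (3.004). Ctsg (3.34), H2ac8 (3.33), Tmed6 (2.96), Mpo (2.87), Prtn3 (2.86), Upp1 (2.85) and Ms4a3 (2.75) followed. Apoe fell from 2183 to 404 FPKM (-2.43) and Ccr2 from 167 to 37.4 FPKM (-2.13), behind Hspa1a (-3.57), Cd209a (-3.25) and Atf3 (-2.59). Tmem254b and Tmem254c, paralogs that share sequence, stood at the 2 ends, with Tmem254b not listed in T-ALL and taken as 0. Of 8371 genes compared 1002 differed at least 2-fold, 629 higher and 373 lower. The neutrophil list had a median of 1.55 (percentile 100 of random lists), the natural killer cell list -1.42 (percentile 0) and the class II list -1.03 (percentile 0). Comparisons within a subset rest on 1 library per state and have no replicate check.

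Within Ly6CloF480lo, red cell genes were among those with the largest increases. Mcpt8, a basophil protease, went from 7.43 FPKM in normal to 106 FPKM in T-ALL (log2 3.66, 1 library per state). Cldn13 (3.63), Ctsg (3.59), Mpo (3.53), Asns (3.46), Slc4a1 (3.44), Hbb-bs, a globin (3.44), and Prss34 (3.39) were close behind, and H2ac11 was not listed in normal and was taken as 0. Egr1, an immediate early transcription factor, fell from 307 to 52.9 FPKM (-2.52), after Atf3 (-3.19) and ahead of Rhob (-2.15), Mmp12 (-2.12), S100a9 (-2.09), Mmp9 (-2.08) and Ngp (-1.94). Of 8767 genes compared 632 differed at least 2-fold, 499 higher and 133 lower. The erythroid list had a median of 2.87 (percentile 100) and the neutrophil list -1.59 (percentile 0).

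Within Ly6CloF480hi, red cell genes increased and single transcripts nearly vanished. Tmem220, a membrane protein gene, went from 694 FPKM in normal to 1.82 FPKM in T-ALL (log2 -7.94, 1 library per state), Podn from 51.1 to 0.65 FPKM (-4.98) and Mpzl1 from 121 to 18.6 FPKM (-2.64). Serpina1a (-4.03), Kcnj15 (-2.97), Hspb7 (-2.72), Tmem37 (-2.47) and Hspa1a (-2.46) also fell, as did Pate9 and Mfsd4b5, members of gene families with similar sequences. Apol11b went from 2.99 to 126 FPKM (4.996), followed by Add2, a membrane skeleton gene of red cells (3.94), Slc4a1 (3.92), Aqp1 (3.91), Cldn13 (3.90), Rhag (3.88), Ces2g (3.87) and C1qtnf12 (3.86). Of 8905 genes compared 1541 differed at least 2-fold, 959 higher and 582 lower, the most of the 3 subsets. The erythroid list had a median of 3.02 (percentile 100), the cell cycle list 2.29 (percentile 100), the T cell list 0.88 (percentile 100), the red pulp list -1.19 (percentile 0) and the immediate early list -1.33 (percentile 0).

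The changes were shared between subsets, most of all between the Ly6Clo subsets. Between Ly6CloF480lo and Ly6CloF480hi the log2 changes of 9537 genes had a Pearson r of 0.72 (Spearman rho 0.68), between Ly6ChiF480lo and Ly6CloF480hi 0.60 (0.63), and between Ly6ChiF480lo and Ly6CloF480lo 0.54 (0.57). At 2-fold, 448 genes were higher in both Ly6Clo subsets (58.0 by chance) and 86 lower (9.84). For Ly6ChiF480lo the shared numbers were 258 higher (38.6 by chance) and 57 lower (6.82) with Ly6CloF480lo, and 394 higher (70.3) and 125 lower (25.3) with Ly6CloF480hi. Opposite 2-fold changes numbered 6, 14 and 13 in these pairs. In all 3 subsets 232 genes were higher (4.06 by chance) and 43 lower (0.422). The pairs shared no library but may share mice or sort day, which could give the same agreement.

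For Ly6CloF480hi against Ly6ChiF480lo over the 2 states, many complement and red pulp genes were higher and many neutrophil genes lower. C1qc, a chain of complement C1q, stood at 2539 and 1306 FPKM in normal and T-ALL Ly6CloF480hi and at 66.7 and 42.8 FPKM in Ly6ChiF480lo (log2 5.06, SE 0.26, adjusted p = 5.3e-04, 2 libraries per subset). Cd5l, a secreted macrophage protein, stood at 509 and 547 against 18.8 and 14.7 FPKM (4.91, SE 0.23, adjusted p = 4.6e-04). S100a8 went the other way, with 144 and 92.7 FPKM against 5836 and 21584 FPKM (-6.59, SE 0.82, adjusted p = 0.00706). Vcam1 (4.89), C1qa (4.83), Mertk (4.78), Slc45a3 (4.72), the integrin gene Itgad (4.68), C6 (4.64), Fcna (4.63) and C1qb (4.59) were also higher. Camp, an antimicrobial peptide gene (-6.96, SE 0.69, adjusted p = 0.00350), Ltf, the lactoferrin (-6.82, SE 0.61), Ngp (-6.81), Lcn2 (-6.74), Chil3 (-6.72, SE 0.50), S100a9 (-6.42, SE 0.87), Cd177 (-5.82) and Chil1 (-5.12) were lower. Among the genes followed in every comparison Adgre1 was higher (2.44, adjusted p = 0.00377), and Ly6c2 (-5.66, SE 0.33, adjusted p = 5.7e-04), Ly6c1 (-1.99, adjusted p = 0.0129) and Itgam (-3.03, adjusted p = 0.00108) were lower. Of 11616 genes 1485 passed, 825 higher and 660 lower, 1209 of them at least 2-fold. The median of all genes was 0.12 and became 0.00 after quantile normalization and 0.03 with the length and GC trend removed, where the split was 549 higher and 739 lower and 637 higher and 760 lower. With a single library left out, the other library of its subset was assumed to vary like the other groups. The count was 984 without normal Ly6ChiF480lo, 617 without normal Ly6CloF480hi and 835 without T-ALL Ly6ChiF480lo. Without normal Ly6CloF480hi, Camp, Ngp, Lcn2, S100a8 and S100a9 did not pass (adjusted p = 0.0617, 0.0635, 0.0704, 0.0875 and 0.0985). These are the highest of 15 alternatives, the lowest lay between 0.00155 and 0.00193, and the log2 stayed between -8.26 and -4.74. Without the state block Itgad and Fcna did not pass (adjusted p = 0.0552 and 0.0701).

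Lists followed these genes, and the complement and phagocytosis lists share members with the red pulp list. Of 24 red pulp and iron genes 20 were higher and 0 lower in Ly6CloF480hi than in Ly6ChiF480lo (22 and 0 over the list alone, 4 did not pass, median 3.47, camera adjusted p = 7.4e-19, adjusted p = 0.578 with an estimated correlation). Of 12 complement genes 7 were higher, 3 lower and 2 did not pass (7 and 3 over the list alone, median 1.79, camera adjusted p = 0.00823, adjusted p = 0.578 with an estimated correlation), with C2 at 3.73 beside the C1q genes. Of 25 phagocytosis and lysosome genes 10 were higher, 1 lower and 14 did not pass (14 and 1 over the list alone, median 0.70, camera adjusted p = 4.4e-04, adjusted p = 0.790 with an estimated correlation), including Axl (4.01) and the lysosomal protease gene Ctsd (2.36, adjusted p = 0.00574). Of 16 erythroid genes 12 were higher, 0 lower and 4 did not pass (16 and 0 over the list alone, median 3.69, camera adjusted p = 5.1e-08, adjusted p = 0.703 with an estimated correlation), led by Epor, the erythropoietin receptor (4.12, SE 0.64, adjusted p = 0.0144), so this marker group moved with the red pulp genes. Of 13 neutrophil genes 0 were higher and 11 lower (0 and 12 over the list alone, 2 did not pass, median -4.79, camera adjusted p = 8.6e-13, adjusted p = 0.578 with an estimated correlation). Of 15 classical monocyte genes 0 were higher and 11 lower (0 and 12 over the list alone, 4 did not pass, median -1.75, camera adjusted p = 3.1e-13, adjusted p = 0.578 with an estimated correlation), with Hp (-4.61, SE 0.21) and the lysozyme gene Lyz2 (-3.57). Of 17 patrolling monocyte genes 0 were higher and 11 lower (0 and 12 over the list alone, 6 did not pass, median -1.54, camera adjusted p = 4.9e-10, adjusted p = 0.578 with an estimated correlation), with Ace (-4.08, SE 0.53) and the chemokine receptor gene Cx3cr1 (-3.22, SE 0.37). Plasma cell genes (0 higher and 5 lower of 7; 0 and 7 over the list alone, median -2.96, camera adjusted p = 7.3e-09, adjusted p = 0.578 with an estimated correlation; Jchain -4.08) moved with them.

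Smaller lists separated Ly6CloF480hi from Ly6ChiF480lo as well. Elane, the neutrophil elastase, was lower (log2 -4.86), as was Siglech, a lectin of plasmacytoid dendritic cells (-3.39). Of 10 myeloid progenitor genes 1 was higher and 6 lower (3 and 7 over the list alone, median -3.67, camera adjusted p = 1.9e-04), and of 10 plasmacytoid genes 0 and 7 (0 and 8, median -1.37, 7.0e-07). Of 11 natural killer cell genes 0 were higher and 4 lower (0 and 6, median -1.15, 2.3e-05), among them the granzyme gene Gzma (-1.79, adjusted p = 0.0277) and the perforin gene Prf1 (-1.73). Migration (3 higher and 6 lower of 19, 4 and 10 over the list alone, median -0.64, camera adjusted p = 0.00143), glycolysis (0 and 4 of 17, 1 and 6, -0.31, 0.00484), cholesterol synthesis (0 and 1 of 14, 0 and 2, -0.46, 3.3e-04) and stress lists (0 and 3 of 16, 0 and 3, -0.76, 4.4e-04) were called lower. The T cell list was called lower too (0 and 2 of 18, 0 and 2, -0.45, 0.0243) but not without normal Ly6ChiF480lo or normal Ly6CloF480hi. The class II list (4 and 0 of 14, 5 and 0, 0.31, 0.0368) was called higher but not without T-ALL Ly6ChiF480lo or T-ALL Ly6CloF480hi, and the B cell list (2 and 0 of 13, 8 and 1, 0.77, 0.0368) was called higher but not without normal Ly6ChiF480lo or T-ALL Ly6CloF480hi. With an estimated correlation these lists had an adjusted p between 0.578 and 0.886.

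For Ly6CloF480lo against Ly6ChiF480lo over the 2 states, some genes of dendritic and B cells were higher and many of the same neutrophil genes lower. Apol7c, an apolipoprotein L gene, stood at 204 and 85.9 FPKM in normal and T-ALL Ly6CloF480lo and at 18.6 and 3.89 FPKM in Ly6ChiF480lo (log2 3.77, SE 0.22, adjusted p = 0.00433, 2 libraries per subset). Fscn1, an actin bundling protein of mature dendritic cells, stood at 58.1 and 57.5 against 8.08 and 5.07 FPKM (2.99, SE 0.33, adjusted p = 0.0122). Ppp1r14a (3.78, SE 0.23), Car1 (4.12, SE 0.46), H2-M2 (3.21, SE 0.27), Asb2 (3.14), Tbc1d4 (3.09), Cacnb3 (3.04), Ube2e2 (3.01) and Klri1 (2.95) were also higher. Camp (-7.28, SE 0.69, adjusted p = 0.00995), Ngp (-7.18), Ltf (-7.04), S100a8 (-7.03, SE 0.82, adjusted p = 0.0155), S100a9 (-6.79), Lcn2 (-6.72), Chil3 (-6.58) and Cd177 (-5.98) were lower, as was Fcnb, which was not listed in T-ALL Ly6CloF480lo and was taken as 0. Ly6c2 (-5.25, SE 0.33, adjusted p = 0.00442), Ly6c1 (-2.13, adjusted p = 0.0232) and Itgam (-1.65, adjusted p = 0.0184) were lower, and Adgre1 did not pass (0.32, adjusted p = 0.455). Of 11616 genes 549 passed, 311 higher and 238 lower, 508 of them at least 2-fold. The median of all genes was 0.19, and it was 0.02 after median-ratio rescaling, 0.04 after quantile normalization and 0.00 with the length and GC trend removed, where the split was 173 higher and 274 lower, 161 and 239, and 171 and 298. The count was 0 without the state block, 81 without normal Ly6CloF480lo, 137 without T-ALL Ly6ChiF480lo and 225 without T-ALL Ly6CloF480lo. Without normal and without T-ALL Ly6CloF480lo these genes did not pass: Car1 (adjusted p = 0.189 and 0.129), Fscn1 (0.108 and 0.0555), Camp (0.0616 and 0.0592), Ngp (0.0751 and 0.0659), Ltf (0.0822 and 0.0635), S100a8 (0.0939 and 0.0952), S100a9 (0.104 and 0.113), Lcn2 (0.0901 and 0.0867) and Chil3 (0.0716 and 0.0537). S100a9 was also lost without normal Ly6CloF480hi (0.0561), and over 15 alternatives these 9 genes ranged from 0.00131 to 0.374. Their log2 stayed between -8.60 and -5.10 for the lower genes, between 3.27 and 4.98 for Car1 and between 2.48 and 3.49 for Fscn1.

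Among lists, class II, B cell and dendritic cell genes set Ly6CloF480lo apart from Ly6ChiF480lo. H2-Oa, a class II peptide loading regulator, stood at 447 and 234 FPKM against 89.2 and 46.1 FPKM (log2 2.31, SE 0.25, adjusted p = 0.0114). Of 14 class II genes 5 were higher, 0 lower and 9 did not pass (12 and 0 over the list alone, median 1.14, camera adjusted p = 1.6e-05, adjusted p = 0.462 with an estimated correlation). Of 14 conventional dendritic cell genes 7 were higher, 1 lower and 6 did not pass (10 and 1 over the list alone, median 1.19, camera adjusted p = 0.00118, adjusted p = 0.462 with an estimated correlation), including Esam (2.67, SE 0.18, adjusted p = 0.00621), the homing receptor gene Ccr7 (2.27, SE 0.23, adjusted p = 0.0107) and Zbtb46 (2.04, SE 0.25, adjusted p = 0.0154). Of 13 B cell genes 7 were higher, 0 lower and 6 did not pass (11 and 0 over the list alone, median 1.38, camera adjusted p = 2.4e-05, adjusted p = 0.462 with an estimated correlation), with Cr2 (1.79, adjusted p = 0.0244), Blk (1.60), Pax5 (1.54) and Ebf1 (1.504), so B cell markers moved with the class II genes. Of 13 neutrophil genes 10 were lower and 0 higher (0 and 13 over the list alone, 3 did not pass, median -4.39, camera adjusted p = 1.0e-17, adjusted p = 0.462 with an estimated correlation), and of 15 classical monocyte genes 9 were lower and 0 higher (0 and 11 over the list alone, 6 did not pass, median -1.78, camera adjusted p = 8.0e-12, adjusted p = 0.462 with an estimated correlation). Of 15 general macrophage genes 4 were lower and 0 higher (0 and 4 over the list alone, 11 did not pass, median -0.62, camera adjusted p = 3.0e-07, adjusted p = 0.462 with an estimated correlation). The red pulp list was not called (0 of 24 passed, by either adjustment; median -0.05, camera adjusted p = 0.163).

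Further lists were lower in Ly6CloF480lo than in Ly6ChiF480lo. C3, the central complement component, was lower (log2 -2.40, SE 0.17, adjusted p = 0.00661) and Msr1, a scavenger receptor, was lower as well (-2.21, adjusted p = 0.0178). Plasma cell genes (0 higher and 6 lower of 7, 0 and 6 over the list alone, median -2.58, camera adjusted p = 3.6e-11) and phagocytosis and lysosome genes (0 and 4 of 25, 0 and 8, -0.43, 4.8e-09) were called lower. So were the plasmacytoid (1 and 5 of 10, 1 and 7, -1.15, 1.8e-06), type I interferon (0 and 2 of 30, 0 and 4, -0.25, 3.6e-06), patrolling monocyte (0 and 1 of 17, 0 and 1, -0.68, 8.3e-06), cholesterol synthesis (0 and 1 of 14, 0 and 1, -0.43, 2.2e-05), stress (0 and 3 of 16, 1 and 5, -0.69, 7.3e-05), myeloid progenitor (3 and 6 of 10, 3 and 6, -2.26, 0.00308) and migration lists (3 and 2 of 19, 4 and 4, -0.55, 0.00792). Other calls hung on single libraries. Ribosomal genes were called higher (0 and 0 of 34 by either adjustment, 0.78, 4.4e-06) but not without normal Ly6CloF480lo. Erythroid (1 and 0 of 16, 3 and 0, 1.58, 0.00595) and NF-kB genes (2 and 0 of 14, 5 and 0, 0.47, 0.0290) were called higher but not without T-ALL Ly6ChiF480lo or T-ALL Ly6CloF480lo. Natural killer genes (0 and 0 of 11 by either adjustment, -0.29, 0.0130) were called lower but not without normal Ly6ChiF480lo or normal Ly6CloF480lo, and T cell genes (1 and 1 of 18, 4 and 2, -0.32, 0.0290) not without normal Ly6ChiF480lo or T-ALL Ly6CloF480lo. Glycolysis genes (1 and 0 of 17, 2 and 3, median -0.26, mean -0.06, 0.0279) were called lower although the 1 that passed was higher, but not without normal Ly6ChiF480lo, normal Ly6CloF480lo or T-ALL Ly6CloF480lo. With an estimated correlation these lists had an adjusted p between 0.462 and 0.769.

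For Ly6CloF480hi against Ly6CloF480lo over the 2 states, many red pulp genes were again higher. Mertk, a receptor for apoptotic cells, stood at 164 and 60.8 FPKM in normal and T-ALL Ly6CloF480hi and at 4.76 and 1.34 FPKM in Ly6CloF480lo (log2 4.78, SE 0.21, adjusted p = 5.8e-04, 2 libraries per subset). Axl, a related receptor, stood at 557 and 158 against 20.96 and 6.15 FPKM (4.57, SE 0.17, adjusted p = 5.8e-04). Vcam1 (4.71), C6 (4.48), Cd5l (4.45), Itgad (4.42), C1qa (4.42), C1qc (4.42) and C1qb (4.37) were higher too. Pglyrp1, a peptidoglycan recognition protein gene, stood at 29.0 and 38.8 against 109 and 144 FPKM (-1.87, SE 0.17, adjusted p = 0.00360). Hp (-1.84, SE 0.21), Ly6i (-2.25, SE 0.37), Krt80 (-2.17, SE 0.39), Arhgef10l (-2.06), the lactate carrier gene Slc16a3 (-1.96), Ceacam1 (-1.92), Skint3 (-1.84) and G0s2 (-1.84, SE 0.24) were lower, as was the multigene family member H2ac22, not listed in either Ly6CloF480hi library and taken as 0. Adgre1 was higher (2.12, adjusted p = 0.0123), Itgam was lower (-1.38, adjusted p = 0.0289), and Ly6c2 (-0.41, adjusted p = 0.555) and Ly6c1 (0.15, 0.834) did not pass. Of 11616 genes 414 passed, 309 higher and 105 lower, 400 of them at least 2-fold. The median of all genes was -0.10, and 0.00 after median-ratio rescaling. The count was 0 without the state block, 127 without normal Ly6CloF480lo, 149 without normal Ly6CloF480hi and 668 without T-ALL Ly6CloF480hi.

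Of the lower genes of this comparison Pglyrp1 passed whichever library was left out (log2 -1.90 to -1.76 over 15 alternatives) but not without the state block (adjusted p = 0.128). Others kept their direction but not their calls, and for H2ac22, taken as 0 in one subset, the size of the change rests on the pseudocount and is not given. Ly6i, Krt80, Slc16a3, Ceacam1, Skint3 and Arhgef10l did not pass without normal Ly6CloF480lo (adjusted p = 0.257, 0.282, 0.0950, 0.178, 0.116 and 0.175), without normal Ly6CloF480hi (0.234, 0.337, 0.301, 0.307, 0.108 and 0.4003) or without T-ALL Ly6CloF480lo (0.176, 0.219, 0.119, 0.160, 0.0759 and 0.193). H2ac22 was lost without normal Ly6CloF480lo (0.131), normal Ly6CloF480hi (0.222) or T-ALL Ly6CloF480hi (0.0573), Arhgef10l also without T-ALL Ly6CloF480hi (0.0527), and Hp (0.0671) and G0s2 (0.0687) without normal Ly6CloF480hi. Over 15 alternatives the highest adjusted p was 0.406 for Hp, 0.275 for Ly6i, 0.337 for Krt80, 0.4003 for Arhgef10l, 0.301 for Slc16a3, 0.307 for Ceacam1, 0.235 for Skint3, 0.222 for H2ac22 and 0.103 for G0s2, with lowest values between 0.00237 and 0.0118. Over the same alternatives the log2 ran from -2.76 to -1.73 for Ly6i, from -2.65 to -1.69 for Krt80, from -2.46 to -1.67 for Arhgef10l and from -2.33 to -1.60 for Slc16a3. It ran from -2.29 to -1.54 for Ceacam1, from -2.21 to -1.52 for Skint3, from -2.09 to -1.59 for Hp and from -2.21 to -1.47 for G0s2. Of 24 red pulp and iron genes 19 were higher, 0 lower and 5 did not pass (24 and 0 over the list alone, median 3.63, camera adjusted p = 4.7e-38, adjusted p = 0.428 with an estimated correlation). Of 12 complement genes 8 were higher, 0 lower and 4 did not pass (9 and 1 over the list alone, median 2.04, camera adjusted p = 4.1e-09, adjusted p = 0.428 with an estimated correlation). Of 25 phagocytosis and lysosome genes 14 were higher, 0 lower and 11 did not pass (20 and 1 over the list alone, median 1.27, camera adjusted p = 2.3e-20, adjusted p = 0.615 with an estimated correlation), with Fcgr1 (2.99, adjusted p = 0.00579) and Ctsd (2.72). Of 16 erythroid genes 2 were higher, 0 lower and 14 did not pass (8 and 0 over the list alone, median 1.84, camera adjusted p = 6.0e-07, adjusted p = 0.615 with an estimated correlation), which were Hba-a2 (3.81, adjusted p = 0.0441) and Hbb-b1 (3.18, adjusted p = 0.0115), globin genes that share sequence. Of 17 patrolling monocyte genes 4 were lower and 0 higher (1 and 12 over the list alone, 13 did not pass, median -1.19, camera adjusted p = 4.4e-05, adjusted p = 0.615 with an estimated correlation), and of 14 conventional dendritic cell genes 2 were lower, Flt3 (-1.38, adjusted p = 0.0427) and Itgax (-1.26, adjusted p = 0.0203), and 0 higher (0 and 7 over the list alone, 12 did not pass, median -0.76, camera adjusted p = 9.9e-05, adjusted p = 0.615 with an estimated correlation).

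The remaining lists of this comparison followed the same line. Of 15 general macrophage genes 6 were higher and 1 lower (8 and 3 over the list alone, median 1.20, camera adjusted p = 5.4e-05), of 11 cholesterol efflux genes 3 and 0 (4 and 0, 0.44, 9.9e-05) and of 18 checkpoint and suppression genes 4 and 1 (6 and 2, 0.26, 0.00142). Called lower were the myeloid progenitor (0 and 2 of 10, 0 and 9, -1.22, 1.1e-04), classical monocyte (0 and 2 of 15, 0 and 7, -0.54, 0.00679), B cell (0 and 0 of 13 by either adjustment, -0.58, 6.8e-04) and ribosomal lists (0 and 0 of 34 by either adjustment, -0.69, 2.2e-07). The class II list was called lower (median -0.82, mean -0.47, 0.00832), although 1 of 14 genes passed as higher and 0 as lower (1 and 7 over the list alone). NF-kB (0 and 1 of 14, 0 and 2, -0.46, 0.0188) and natural killer cell genes (0 and 0 of 11 by either adjustment, -0.89, 0.00679) were called lower but not without T-ALL Ly6CloF480lo. Type I interferon genes (0 and 0 of 30 by either adjustment, 0.16, 0.0341) were called higher but not without normal Ly6CloF480lo, normal Ly6CloF480hi or T-ALL Ly6CloF480hi. With an estimated correlation these lists had an adjusted p between 0.615 and 0.677.

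**Figure D3:**
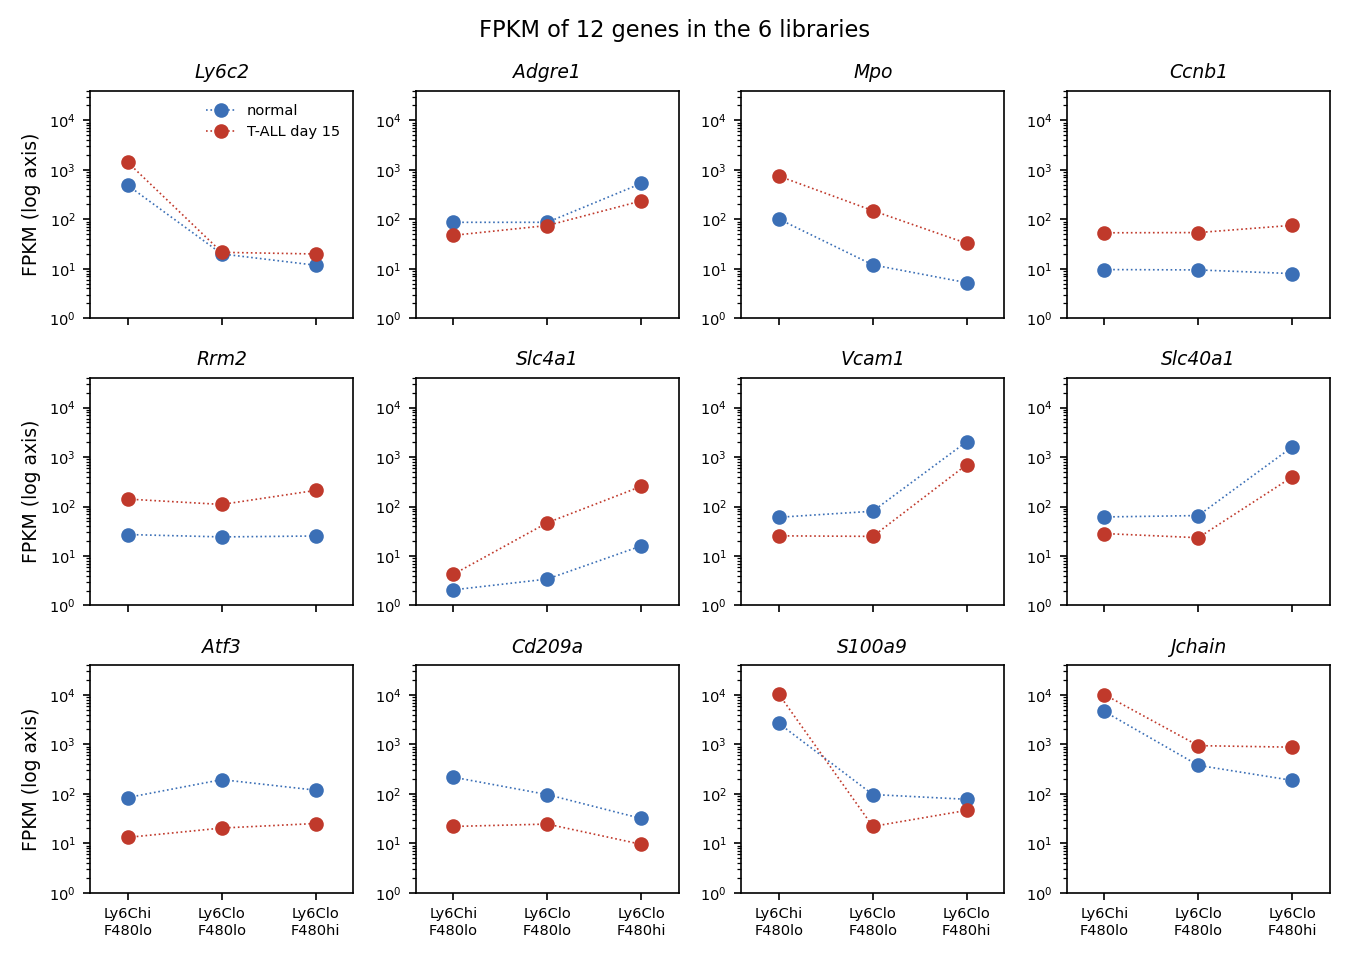
FPKM, on a log axis, of 12 genes in the 6 libraries (blue normal, red T-ALL; dotted lines only guide the eye), among them Ly6c2, Adgre1, Mpo, Ccnb1, Slc4a1, Vcam1, Atf3 and Jchain.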

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

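Changes that differed in direction between subsets were looked for among 39 lists and 411 named genes. A list counted when its median change lay in the upper tail of matched random lists in one subset and in the lower tail in another, and a gene when it was at least 2-fold higher in one and at least 2-fold lower in another. There were 3 such lists and 10 such genes. No group has 4 or more samples, so single samples were not compared with their group. None of these differences between subsets was tested, since each rests on 1 library per state and subset.

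Neutrophil genes differed most between Ly6ChiF480lo and Ly6CloF480lo. The neutrophil list had a median change of 1.55 in Ly6ChiF480lo and -1.59 in Ly6CloF480lo, a difference of 3.15. Among its members were Retnlg (3.004 against -2.26, difference 5.27), S100a9 (1.96 against -2.09, 4.05), Mmp9 (1.76 against -2.08, 3.84), S100a8 (1.89 against -1.91, 3.79), Lcn2 (1.93 against -1.54, 3.46), Camp (1.47 against -1.79, 3.26), Ngp (1.31 against -1.94, 3.26) and Ltf (1.14 against -1.59, 2.74). Chil3, a monocyte gene outside that list, differed as well (1.08 against -1.05, 2.13). S100a9 stood at 2653 FPKM in normal and 10296 FPKM in T-ALL Ly6ChiF480lo, and at 96.8 and 21.9 FPKM in Ly6CloF480lo.

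The T cell list had a median change of 0.88 in Ly6CloF480hi and -0.59 in Ly6ChiF480lo (difference 1.48). The patrolling monocyte list had 0.48 in Ly6CloF480lo and -0.62 in Ly6ChiF480lo (difference 1.10). Fn1, which encodes fibronectin, was higher in T-ALL in Ly6CloF480hi (1.77) and lower in Ly6ChiF480lo (-1.18), a difference of 2.95.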

How the results depend on the processing

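The number of genes that passed in T-ALL against normal over the 3 subsets was 1410, and it depended mainly on the filter, the block and the number of libraries. Without a filter on low values 370 passed, and with a 2-fold threshold, which keeps a part of the same genes by construction, 621. Without the subset block 161 passed (2024 had an unadjusted p under 0.05). With 1 library left out the count ran from 283 to 923, and without the Ly6ChiF480lo, Ly6CloF480lo or Ly6CloF480hi pair it was 885, 851 and 326, of which 673, 648 and 313 had passed before. These fits have fewer residual degrees of freedom. A pseudocount of 0.1 (1687), a mean of at least 5 FPKM (1433), median-ratio rescaling (1374), quantile normalization (1290), limma without trend and robust prior (1094) and removal of the length and GC trend (1160) stayed within 1.5 times.

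Between subsets, without a filter 867 genes passed for Ly6CloF480hi against Ly6ChiF480lo over the 2 states (main 1485), 156 for Ly6CloF480lo against Ly6ChiF480lo over the 2 states (549) and 173 for Ly6CloF480hi against Ly6CloF480lo over the 2 states (414). Without the state block the limma counts were 197, 0 and 0 (1877, 1335 and 1179 genes with an unadjusted p under 0.05). With 1 library left out they ran from 617 to 1277, from 81 to 718 and from 127 to 668. The cause of the drop without filter or block was not tested.

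Within subsets, a limit of 20 FPKM gave 654, 310 and 926 genes at 2-fold for T-ALL against normal in Ly6ChiF480lo, T-ALL against normal in Ly6CloF480lo and T-ALL against normal in Ly6CloF480hi (main 1002, 632 and 1541), and a 4-fold limit gave 93, 116 and 294, in each case by keeping fewer genes. Correlations between subsets and shares of variance stayed the same in every alternative.

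For gene lists in T-ALL against normal over the 3 subsets camera called 17 of 39 (8 higher and 9 lower), and for gene lists between subsets over the 2 states 56 results (20 higher and 36 lower). With an estimated correlation it called 0 and 0, and fry called 0 and 5. The estimated form uses the 2 residual degrees of freedom, which raises p, and calls were also lost at correlations below 0. For complement genes in Ly6CloF480hi against Ly6CloF480lo (-0.036) the camera p went from 3.1e-10 to 0.022. Other called lists had high correlations (cell cycle 0.70, erythroid 0.90), for which the preset 0.01 gives too low a p. Fry has a lowest adjusted p of 0.0950 between states.

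Of 88 results on named genes, with 1375 alternative values in all, 86 never changed direction. Apart from the genes named whatever their change, these genes were chosen for the same direction in every pair. Leaving out a library or pair could therefore hardly reverse them, and the count does not measure stability. Those that reversed, Ly6c1 and Itgam, were among the genes named whatever their change. Ly6c1 (main 0.18) became -0.084 without the Ly6ChiF480lo pair and -0.036 with the length and GC trend removed, and ran from -0.084 to 0.47 with 1 library left out. Itgam (main -0.16) became 0.064 without the Ly6ChiF480lo pair and ran from -0.27 to 0.064 with 1 library left out. Neither passed in any of these, and the cause was not tested. Leaving out pairs and removing the length and GC trend (available for 11567 of 11616 genes, 99.6%) were added after the data were seen. The counting error of a gene of 1 FPKM (24.0% to 27.4%) limits what can be said of weakly expressed genes.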

Other observations

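Mcpt8, a basophil protease, rose between states (log2 2.54, adjusted p = 0.0214) together with Prss34 (2.70, adjusted p = 0.0225), and no list of basophil or mast cell genes was tested. Prg2, a granule protein of eosinophils, rose from 49.2, 12.03 and 7.28 FPKM in normal to 130.4, 107 and 23.3 FPKM in T-ALL (1.999, SE 0.33, adjusted p = 0.0218; 3 libraries per state) and Epx, the eosinophil peroxidase, rose (1.26, adjusted p = 0.0424), while the chemokine receptor gene Ccr3 fell from 7.39, 9.13 and 264 FPKM to 2.47, 2.77 and 57.1 FPKM (-1.63, SE 0.21, adjusted p = 0.0116). Of 8 eosinophil genes 2 rose, 1 fell and 5 did not pass (4 and 2 over the list alone, median 0.68, camera adjusted p = 0.253, adjusted p = 0.581 with an estimated correlation). Of 11 natural killer cell genes Klrk1 fell (-0.96, adjusted p = 0.0489), of 10 plasmacytoid dendritic cell genes Cd300c (-0.88, adjusted p = 0.0371) and of 5 endothelial genes Stab2 (-0.9996, adjusted p = 0.0411), and none of these lists was called (camera adjusted p = 0.141, 0.114 and 0.501). Of 13 B cell genes 0 passed over all genes, and over the list alone 1 rose and 3 fell (median -0.32; camera adjusted p = 0.115, adjusted p = 0.719 with an estimated correlation). Without normal or T-ALL Ly6CloF480hi the eosinophil list was called higher and the B cell (also after quantile normalization), natural killer and plasmacytoid lists lower, and the natural killer list also without normal or T-ALL Ly6CloF480lo.

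The T cell list was higher in T-ALL in Ly6CloF480hi alone (medians -0.59, -0.32 and 0.88 in Ly6ChiF480lo, Ly6CloF480lo and Ly6CloF480hi). Dntt, the terminal transferase of immature lymphocytes, went from 0.38 FPKM in normal to 16.5 FPKM in T-ALL (1 library per state; log2 3.67), Thy1 from 0.60 to 6.65 FPKM (2.26), Tcf7 from 2.60 to 15.4 FPKM (2.19) and Cd3e, a chain of the T cell receptor complex, from 2.22 to 10.8 FPKM (1.88).

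Calls between states were compared with those of other splits of the libraries, a test chosen only after the result was seen. Of 10 splits into 3 and 3, with subset as a block, the real one called 1410 genes and the others at most 1. In those others state adds to the residual, so low counts were built in and decide nothing. Only 4 splits part all 3 pairs, so no share under 0.05 can be reached.

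Higher cell cycle genes in all 3 subsets: all tests were chosen only after the result was seen, and for length and GC alone the prediction was written before the corrected value was seen. Erythroid cells may bring cell cycle transcripts, yet in Ly6ChiF480lo the cell cycle median lay 1.55 above the erythroid one (95% interval 1.07 to 1.90 over 10000 resamplings of the genes, which are not replicates), and FPKM added in Ly6CloF480hi over Ly6CloF480lo differed by -1.42 between the lists (-2.20 to -0.45; 25 and 16 genes), where a single erythroid source of one makeup would give 0, which leaves erythroid cells of different stages open. Leukemic T cells may bring them too. The cell cycle list exceeded the T cell list by 2.43 in Ly6ChiF480lo (2.01 to 2.82) and 1.89 in Ly6CloF480lo (1.53 to 2.22). The T cell median was above 0 only in Ly6CloF480hi, where the excess was 1.41 (0.87 to 2.05). Normal T cells share these markers and their loss could mask leukemic ones, so this source stays open. With the length and GC trend removed the median stayed at 1.78 (1.61 to 2.11), and myeloid progenitors and plasma cells, whose lists were above 0 in all 3 subsets (medians 2.46, 2.45 and 1.36, and 1.20, 0.76 and 2.10), were not tested as sources and stay open. Of 16 erythroid genes 13 and of 18 T cell genes 15 reach 1 FPKM in all normal libraries, 0 are in another list, Hba-a1 stood at 399, 2579 and 18610 FPKM in T-ALL and the most abundant T cell genes Cd2 and Lck at 49.3 and 32.3 FPKM in T-ALL Ly6CloF480hi, and a gate that excludes Ter119 and CD3 or GFP would remove such cells.

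Lower red pulp genes in Ly6CloF480hi: all tests were chosen only after the result was seen, and for length and GC alone the prediction was written before the corrected value was seen. A lower share of macrophages in the gate may dilute their transcripts, and although the erythroid median lay 2.95 above that of the B cell list (95% interval 2.74 to 3.54; 3.02 against 0.07), where cells of every type would rise alike, 5 of 13 lists of other cell types were in the upper tail of random lists (erythroid, plasma cell 2.10, myeloid progenitor 1.36, megakaryocyte and platelet 0.98 and T cell 0.88), so the cells that enter need not be of every type and a lower share cannot be told apart from a change within macrophages. Scaling by abundant globin could lower every other gene, yet all other genes lay 1.21 above the red pulp list (0.91 to 1.54; 0.02 against -1.19). With the length and GC trend removed the median was -1.35 (-1.59 to -1.06). All 24 red pulp genes reach 1 FPKM in every normal library, 10 are in another list, and a change of macrophage state was not tested.

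Lower immediate early genes in all 3 subsets: both tests were chosen only after the result was seen, that of handling with Hspa1a already known, and for length and GC the prediction was written before the corrected value was seen. These genes are induced by tissue handling, and the labels do not separate the day of sorting from state, so longer or warmer handling of the normal spleens may account for them; 6 cytosolic heat shock genes had a median change of 0.16 (95% interval -1.79 to 0.90), with Hspa1a lower (-2.47) and Hsph1 higher (0.95, adjusted p = 0.0228), so handling and a response to disease cannot be told apart. With the length and GC trend removed the median was -0.98 (-1.17 to -0.60).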
